A study of Mus musculus with 4 samples.

How the data were processed

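RNA of CD4 and CD8 splenic T cells was measured by RNA-seq in 4 libraries, 1 for each cell type at and after allogeneic transplant. Per the labels, each library was made with a TruSeq mRNA kit from RNA of 5 pooled mice extracted with an RNeasy kit. Groups were taken from the labels alone: the libraries at transplant carry the word Donor in their titles, and the later libraries carry day 12 in their titles and day 14 in their characteristics. All titles carry the same lane code.

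The deposited values have the unit signal: estimated reads per gene, scaled in each library so that the upper quartile of the genes above 0 was about 1000. RSEM 1.1.13, SAMtools 1.2 and genome build mm9 were named in the submitters' processing notes, and the aligner, the annotation and the scaling step were not given in the sources used here. The planned analysis allowed counts or normalised values, and the table held normalised values, so the deposited scale was used for all ratios. The table listed 21705 genes by symbol and Entrez identifier, of which 5837 were at 0 in all 4 libraries, and 2 further columns held no header and no values. Each library's values were multiples of a step, the value of 1 read: 0.664, 0.877, 0.826 and 1.41 (CD4 at, CD4 after, CD8 at, CD8 after transplant, the order kept below). Divided by it, the values had at most 2 decimals and were within 0.1 of a whole number for 86.4, 87.2, 87.3 and 87.6% of the genes above 0, so they are estimated reads rather than counts. Depth was 23633544, 16130849, 17972481 and 9873851 estimated reads, and a floor of 3 reads per library stood at 1.99, 2.63, 2.48 and 4.23. The 10 most abundant genes held 5.19, 4.24, 5.61 and 4.52% of the total, and the most abundant, Eef1a1, 1.35, 1.01, 1.58 and 1.10%.

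Log2 ratios were computed after adding 14.7 to each value, which is 1 ppm of the mean library total. Genes were counted as at least 2-fold higher or lower among 9933 genes with a mean over the libraries of at least 5 ppm (73.3). The comparisons were CD4 after against at transplant, CD8 after against at transplant, and CD4 against CD8 at and after transplant. As each group held 1 library there was no test between groups. Ratios of plain values were given with 95% exact conditional binomial intervals on the estimated reads, which cover counting error only. Against a library at 0, a bound was computed at the floor of 3 reads. The similarity of the CD4 and CD8 ratios was given as Pearson's r, Spearman's rho and the share of genes beyond 2-fold in CD4 that passed 2-fold the same way in CD8, with an exact binomial interval that treats genes as independent.

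Gene lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The 40 lists held 628 members, of which 608 were in the table and 542 were measured, with a mean of at least 1 ppm (11627 genes passed this). They covered AhR and its partners, AhR target genes, T cell identity, the CD4 and CD8 lineages, naive, cytotoxic, effector and memory, inhibitory, regulatory, Th1, Th2, Th17 and follicular helper genes, gut homing, chemokines, 2 cell cycle phases, 2 interferon responses, metabolism, ribosomal, stress, immediate early, apoptosis, cytokine receptor, NFkB and housekeeping genes, and 10 kinds of other cells. A list's median log2 ratio was ranked among 10000 random lists of the same size, matched in 20 bins of expression, where at least 4 members were measured. Of 148 list medians 27 had a member at 0 in a library, and 10 moved by more than 0.1 with such members at their bounds, by 1.36 at most. Lists overlap, and genes shared with other lists numbered 4 of 16 for cytotoxic, 11 of 19 for effector surface, 5 of 15 for inhibitory, 7 of 17 for regulatory, 6 of 20 for gut homing and 3 of 18 for naive genes.

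Named genes had a standard symbol, a mean of at least 10 ppm (147) and were no antigen receptor or histocompatibility segment. The rule took the 6 largest ratios each way of the after-against-at comparisons, 5 each way between CD4 and CD8, 4 each way for the difference of the CD4 and CD8 ratios, up to 4 members per list with the largest ratio, the 3 most abundant of each list of other cells, and Ahr, Cd4, Cd8a, Cd8b1, Foxp3 and the measured AhR genes. Genes named beyond the rule serve as members of lists or are said to have been chosen later.

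Alternatives were 4 other scalings (upper quartile, trimmed mean of M-values, median of ratios, equal totals), pseudocounts 0.25 and 4 times as large, and no filter or a stricter filter. Counting intervals wholly beyond 2-fold, and a setting without genes of other cells, were added after the values were seen, and so were gene families outside the lists. That setting left out the members of the 10 lists of other cells. It also left out genes at least 2-fold higher in CD4 than CD8 at transplant that lay within 2-fold either way after it. In all, 9519 genes remained. The procedures were tested on simulated data with 9933 genes per comparison, in which unchanged genes differed by counting error alone and genes were independent. The counting interval held the true ratio for 95.1% (CD4) and 95.5% (CD8) of genes. Of genes simulated at 4-fold 100% passed 2-fold, and 0 unchanged genes did. Of 100 unchanged lists, 4 and 5 fell outside the 2.5 to 97.5 percentile range. Variation between pools of mice was not simulated, so these figures give no rate of false differences between groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

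Raw reads, strand, splicing, gene length and coordinates were not analysed here, and results of some genes are not reported here. Near-identical genes share reads, so the split of values between Ly6c1 and Ly6c2, Hspa1a and Hspa1b, the haemoglobin genes, the Klra and serpin families and class II genes, and between Gapdh and its pseudogenes, is uncertain.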

Results

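Splenic T cells of the C57bl/6 strain were profiled by RNA-seq as a CD4 and a CD8 fraction from a flow sort. Separate libraries came from the day of an allogeneic transplant and from a later day. An allogeneic transplant carries cells between genetically different individuals, and acute graft-versus-host disease arises when donor T cells attack tissues of the recipient. The title of the series concerns the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, and peripherally induced regulatory T cells of the gut. Each of the 4 groups held 1 library, and each library came from a pool of 5 mice made before the sort. The later libraries were taken on day 14 by their characteristics and on day 12 by their titles, and they are called the libraries after transplant here. The libraries at transplant carry the word Donor in their titles. Whether the later libraries hold donor T cells only is not stated in the labels used. A value said to go from 1 level to another compares 2 libraries and does not follow the same cells. None of the 4 libraries is labelled as a transplant between genetically identical mice. Depth was 23633544 and 16130849 estimated reads in the CD4 libraries at and after transplant, and 17972481 and 9873851 in the CD8 libraries. Of 21705 genes, 14749, 14543, 13726 and 14050 were above 0 in these libraries, in that order. Because each group had 1 library, no difference had a replicate check and no p-value was computed. The 95% intervals of ratios cover counting error only. Log2 ratios were taken on the deposited normalised values after adding 14.7, and a gene is called higher or lower where it differed by at least 2-fold on that scale. Ratios printed with a counting interval carry no pseudocount. The percentile of a gene list is the rank of its median log2 ratio among 10000 random lists of the same size and expression, and it describes these libraries only.

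The transcripts of the sorted markers followed the labels. Cd4, the coreceptor of helper T cells, stood at 15134 and 17092 in the CD4 libraries at and after transplant and at 66.1 and 94.5 in the CD8 libraries. Cd8a and Cd8b1, the chains of the coreceptor of killer T cells, stood at 21107 and 22739 in the CD8 library at transplant and at 17999 and 10139.6 after it, against 177 and 435, then 295 and 345, in the CD4 libraries. The source field of the labels names innate lymphoid cells, whereas the cell type field names T cells. Cd3e, a chain of the T cell receptor complex, was abundant in all 4 libraries, at 5272, 4272, 5330.2 and 4807 (CD4 at, CD4 after, CD8 at, CD8 after transplant), and so was Thy1, a surface glycoprotein of T cells, at 14105, 13507, 18962 and 16296.

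In the CD4 libraries, genes of cell division, effector function and inhibitory receptors were higher after transplant, and genes of naive and recirculating T cells were lower. Of 9933 genes with a mean of at least 5 ppm of the mean library total, 1204 were at least 2-fold higher and 1077 at least 2-fold lower after transplant, and 537 and 237 passed 4-fold. The interval of counting error lay wholly beyond 2-fold for 1058 and 869 genes. With library totals set equal in place of the deposited scale, the numbers became 1420 higher and 825 lower, so that the higher share of these genes moved from 52.8% to 63.3%.

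Among named genes with a mean of at least 10 ppm, the 6 with the largest ratio after transplant in the CD4 libraries were Dclk1, Bhlhe40, Gcg, Il21, Ccl4 and Bace2. Bhlhe40, a transcription factor of cytokine-producing T cells, went from 179.9 to 10647 (log2 ratio 5.78). Il21, a cytokine that acts on B cells and T cells, went from 24.6 to 1669, a ratio of 67.9 (95% counting interval 49.1 to 96.8). Ccl4, a chemokine, went from 18.6 to 1403 (log2 ratio 5.41). The other 3 were near the detection floor at transplant. Dclk1, a microtubule-associated kinase, went from 2 reads to 1094, a ratio of 722 (199 to 5970.5). Bace2, an aspartyl protease, went from 1 read to 714, a ratio of 943 (169 to 37283). Gcg (Entrez 14526), the precursor of glucagon and glucagon-like peptide hormones, went from 1 read to 794, a ratio of 1048 (188 to 41454). The 6 with the lowest ratio were Igfbp4, St8sia6, Atp1b1, Slc16a5, Vipr1 and Dapl1. Igfbp4, a binding protein of insulin-like growth factors, went from 12425 to 168 and was 73.8-fold lower (64.0 to 85.5). St8sia6, a sialyltransferase, went from 1220.5 to 6.14, and Vipr1, a receptor of vasoactive intestinal peptide, from 4349 to 94.7. Atp1b1, a sodium pump subunit, Slc16a5, a transporter of the monocarboxylate family, and Dapl1 had log2 ratios of -5.46, -5.45 and -5.29.

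Among genes of naive and recirculating T cells, 17 of 18 were lower after transplant in CD4 and 0 were higher (median log2 ratio -2.57, percentile 0). Ccr7, a chemokine receptor that guides T cells to lymph nodes, went from 7523 to 355. Tcf7, a transcription factor of naive and memory T cells, had a log2 ratio of -2.49, and Bach2, a repressor that holds T cells quiescent, of -4.59. All 22 genes of the G2 and M phases were higher (median 3.97, percentile 100), among them Mki67, a marker of cycling cells, from 752 to 11115 and Ccnb2, a mitotic cyclin, from 110.2 to 2545. Of 20 genes of DNA replication, 18 were higher and 0 lower (median 2.04, percentile 100), with Rrm2, a subunit of ribonucleotide reductase, at a log2 ratio of 3.79.

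Effector genes were higher after transplant in CD4 across several lists. Of 16 cytotoxic effector genes, 10 were higher and 1 lower (median 1.48, percentile 100). Ifng, the cytokine that activates macrophages, went from 61.1 to 2072 and Gzmb, a granule protease, from 179 to 5026, and the median was 1.61 with Gzmf at its bound, whereas Gzma, another granule protease, went from 798 to 353. Of 19 effector surface markers, 14 were higher and 1 lower (median 2.07), including Tnfrsf4, a costimulatory receptor, with a log2 ratio of 3.89 and Il2ra, the high-affinity chain of the interleukin-2 receptor, with 3.74. Of 15 inhibitory receptors and exhaustion genes, 11 were higher and 2 lower (median 2.25, percentile 100), led by Tigit (114 to 4197), Lag3 (119.5 to 3211) and Pdcd1 (248 to 6000.4), receptors that dampen T cell activation. Of 16 effector and memory regulators, 10 were higher and 2 lower (median 1.28), with Prdm1, the gene of Blimp-1, at a log2 ratio of 2.44 and Id3, an inhibitor of E proteins, at -1.66. Of 9 chemokines and colony-stimulating factors, 7 were higher and 0 lower (median 4.34, or 4.80 with Csf2 at its bound). Csf2, the gene of GM-CSF, was at 0 at transplant and at 281 after it, at least 141-fold higher against a floor of 3 reads.

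The 2 CD4 libraries also differed in genes of other cells, which are given here beside the effector lists because NK cells, macrophages and dendritic cells express several of their members. The NK cell list shares 2 of its 13 measured genes with lists of T cell genes and the dendritic cell list 5 of 14, while the macrophage and neutrophil lists share none. Of 13 NK cell genes, 10 were lower after transplant and 3 higher (median -2.12), with Ncr1, an activating receptor of NK cells, at 172 before and 0 after. Of 19 macrophage and monocyte genes 9 were lower and 0 higher (median -0.84), and of 14 dendritic cell genes 9 were lower and 2 higher (median -1.67). Of 13 erythroid and platelet genes 10 were higher and 0 lower (median 1.88), and of 13 neutrophil genes 3 were higher and 2 lower (median 0.72).

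Helper subset genes differed by list in CD4. Of 12 Th1 genes 8 were higher and 0 lower (median 2.40), including Il12rb2, a chain of the interleukin-12 receptor, with a log2 ratio of 4.08 and Tbx21, the gene of T-bet, with 2.34. Of 7 Th2 genes 4 were higher and 1 lower (median 2.52), with Il1rl1, the interleukin-33 receptor, from 61.1 to 1957 and Il4ra, the interleukin-4 receptor chain, from 5329 to 1141. Of 7 Th17 genes 6 were higher and 0 lower (median 2.22), but Il17a was at 0 in all 4 libraries. Of 9 follicular helper genes 5 were higher and 0 lower (median 1.36), with Bcl6, the factor that specifies them, at 439.6 and then 284. Of the measured Th1, Th2, Th17 and follicular helper genes 7, 5, 6 and 4 also stand in other lists. Foxp3 (Entrez 20371), the transcription factor of regulatory T cells, was lower, from 305 to 141 (459 and 161 estimated reads), a ratio of 0.465 (0.385 to 0.555). Its log2 ratio of -1.03 became -0.99, -0.97 and -0.89 under trimmed mean of M-values, median of ratios and equal totals, short of 2-fold. The regulatory T cell list as a whole had 10 of 17 members higher and 3 lower (median 1.42). Its higher members included Il2ra, Ctla4 and Tnfrsf4, which activated T cells also express, and 7 of its members stand in other lists, while Gpr83 (log2 ratio -3.13) and Folr4 (-1.11) were lower with Foxp3. Of 20 genes of gut homing and migration, 8 were higher and 3 lower (median 0.56, percentile 99.89). Cxcr6, a chemokine receptor of effector T cells, had a log2 ratio of 3.22, while Itgb7, a chain of the gut-homing integrin, had -1.12.

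Ahr was higher after transplant in both cell types, whereas 12 of its 15 listed target genes had a mean under 1 ppm. Ahr itself (Entrez 11622) went from 106 to 247 in CD4 (159 and 282 reads) and from 37.2 to 103 in CD8 (45 and 73 reads). The log2 ratios were 1.12 and 1.18, and the ratios of the plain values were 2.34 (1.92 to 2.86) and 2.77 (1.89 to 4.11), so that counting error alone left values on both sides of 2-fold. The log2 ratio fell under 1 with a pseudocount 4 times as large, at 0.90 in CD4 and 0.75 in CD8. Of 8 genes of AhR and its partners, 2 were higher and 0 lower in each cell type (medians -0.36 and -0.19, percentiles 19.6 and 30.1). Besides Ahr this was Arnt2, a dimerisation partner of AhR, from 9.30 to 304 in CD4 and from 1 read to 47 reads in CD8 (ratio 80.3, 13.7 to 3237), while Arnt, the main partner, was at 1218 and 955 in CD4 and 923 and 805 in CD8. Of 15 target genes 3 were measured, too few for a median. Tiparp, a poly-ADP-ribose polymerase that restrains AhR, had log2 ratios of -0.49 and -0.55 in CD4 and CD8. Nqo1, a quinone reductase, had 1.35 and 1.56, and Lpcat2, a lysophospholipid acyltransferase, -1.0 and 1.16. The macrophage and monocyte list also had medians of opposite sign in CD4 and CD8 (-0.84 and 1.28). Which cells of the libraries held the transcripts of Lpcat2, Ahr and the other genes named here was not tested. Cyp1a1, the classical AhR target, had 4 reads or fewer in every library, and Cyp1a2, Cyp1b1 and Il22 were at 0 in all 4.

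Among lists of metabolism and protein synthesis in CD4, the glycolysis median lay above its random range after transplant and the ribosomal protein median below it. Of 17 glycolysis genes 8 were higher and 0 lower (median 0.96), with Hk2, a hexokinase, at a log2 ratio of 2.96 and Tpi1, a triose phosphate isomerase, at 2.77. All 22 genes of oxidative phosphorylation stayed within 2-fold (median 0.24, percentile 98.0). Of 30 cytosolic ribosomal protein genes 9 were lower and 0 higher, and 30 had a log2 ratio below 0 (median -0.90, percentile 0.03). Among 15 heat shock and unfolded protein genes 5 were lower and 0 higher (median -0.36), with Hspa1b, an inducible chaperone, from 2258 to 71.4. Immediate early genes had 3 of 18 higher and 3 lower (median -0.39), with Jun at a log2 ratio of -2.93. Type I interferon genes had 2 of 24 higher and 3 lower (median -0.27), and genes of the interferon gamma response 3 of 20 and 1 (median 0.32), with Gbp3, a guanylate-binding protein, at 2.66. Apoptosis regulators had 5 of 14 higher and 0 lower (median 0.48). NFkB and costimulation genes had 6 of 16 higher and 0 lower (median 0.57), and gamma chain cytokine receptors 3 of 8 higher and 2 lower (median 0.04). T cell identity genes had 2 of 12 lower (median -0.26), among them Lat, an adaptor of receptor signalling (-1.04). The 14 housekeeping genes had a median of -0.13, which became 0.02 with equal library totals, and 2 of them, Gapdh and Pgk1, were higher. The heat shock, immediate early, type I interferon, gamma chain, T cell identity and housekeeping medians lay within their random ranges.

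**Figure D1:**
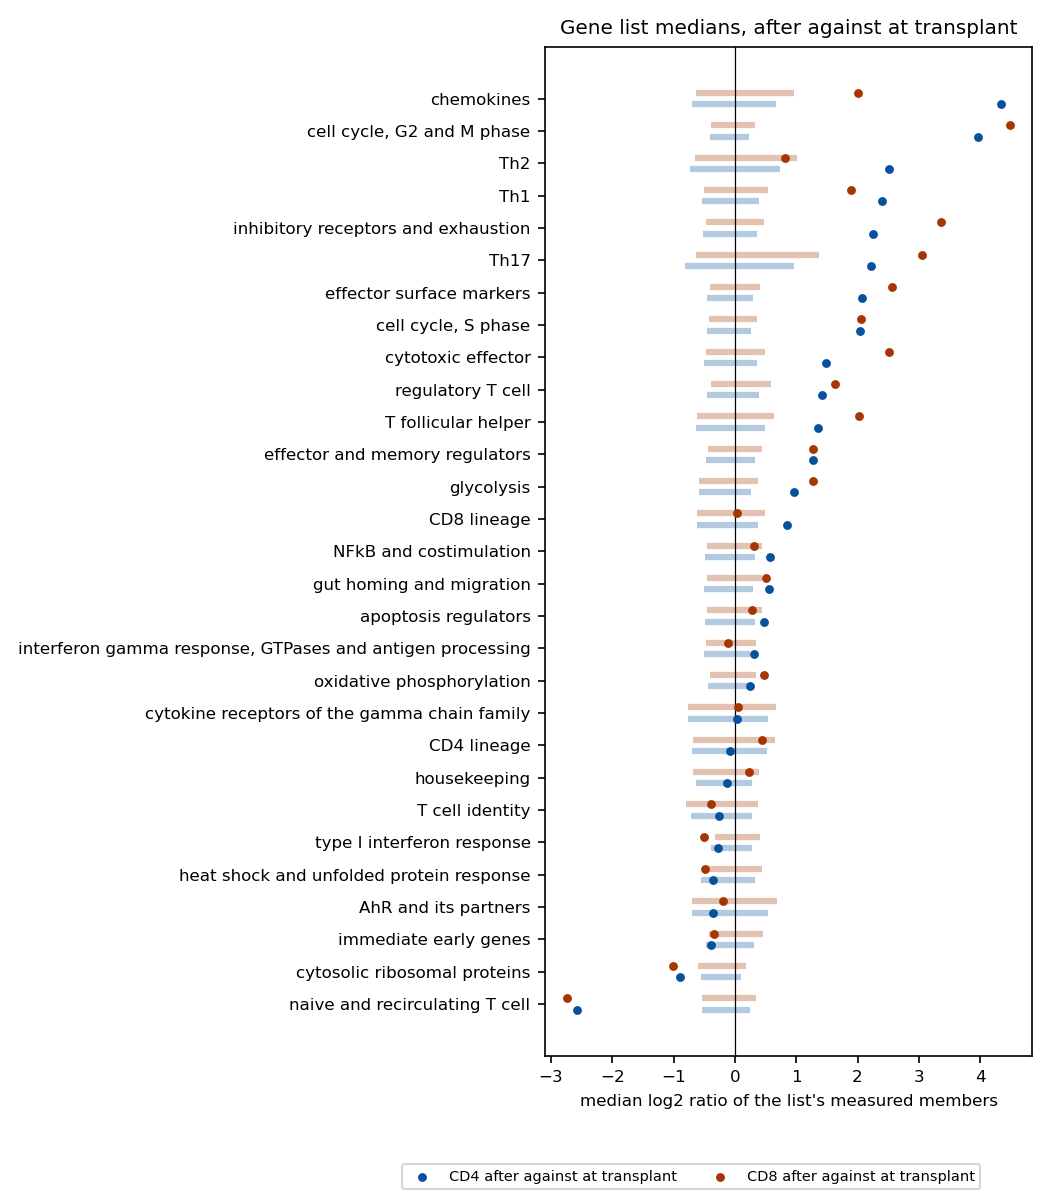
Points give the median log2 ratio of each gene list after against at transplant, in CD4 and in CD8 cells (x axis, log2 units; y axis, lists), and bars the range that holds 95% of 10000 random lists. The G2 and M phase list stood at 3.97 in CD4 and 4.48 in CD8, and the naive list at -2.57 and -2.73, while the medians of housekeeping and CD4 lineage genes in CD4 cells and of CD8 lineage genes in CD8 cells changed sign under other scalings.

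In the CD8 libraries the genes of cell division, cytotoxicity and inhibitory receptors were higher after transplant, and the genes of naive and recirculating T cells were lower. Of 9933 genes 1490 were at least 2-fold higher and 1095 at least 2-fold lower, and 695 and 268 passed 4-fold. The counting interval lay wholly beyond 2-fold for 1277 and 867 genes. Under the trimmed mean of M-values scaling the numbers became 1335 higher and 1274 lower, and with equal library totals 1657 and 963, so that the higher share moved from 57.6% to 51.2% and 63.2%.

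Of the named genes with a mean of at least 10 ppm, Pdcd1, Lag3, Gzmb, Bhlhe40, S100a4 and Ccl3 had the largest ratios in CD8. Pdcd1, the gene of PD-1, went from 45.4 to 8630.5, a ratio of 190.0 (146 to 253). Lag3 went from 37.2 to 5471 and Bhlhe40 from 54.5 to 5654. Gzmb, a granule protease that starts apoptosis in target cells, went from 250.2 to 27271, a ratio of 109 (97.3 to 122). S100a4, a calcium-binding protein, and Ccl3, a chemokine, had log2 ratios of 6.26 and 6.21. Dclk1 and Bace2, high in CD4 after transplant, were at 0 in CD8 at transplant and at 121 and 172 after it, at least 49.0-fold and 69.5-fold higher. The lowest ratios were those of Vipr1, Ccr9, Slc16a5, Sh3pxd2a, Il6ra and Igfbp4. Ccr9, the receptor that guides T cells to the small intestine, went from 3252 to 49.8 and was 65.3-fold lower (47.3 to 94.7). Vipr1 went from 2505 to 26.8 and Il6ra, the interleukin-6 receptor, from 2842 to 60.6. Slc16a5, Sh3pxd2a, a scaffold protein of cell invasion, and Igfbp4 had log2 ratios of -5.51, -5.36 and -5.17.

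Among the genes of naive and recirculating T cells 16 of 18 were lower in CD8 and 0 higher (median -2.73, percentile 0), with Ccr7 from 5753 to 183 and Il7r, the interleukin-7 receptor, at a log2 ratio of -3.12. All 22 genes of the G2 and M phases were higher (median 4.48), and 19 of 20 genes of the S phase (median 2.06), among them Ccnb1, a mitotic cyclin, at 5.67 and Rrm2 at 4.17. Of 16 cytotoxic genes 10 were higher and 1 lower (median 2.52, or 2.74 with Gzmf at its bound). Ifng went from 24 to 2039, Gzma from 461 to 5139.6, and Prf1, the pore-forming perforin, from 1522 to 4925, while Gzmm had a log2 ratio of -2.80. Of 15 inhibitory genes 12 were higher and 1 lower (median 3.36), with Tigit at 6.09, Havcr2, the gene of TIM-3, at 5.66, and Tox, a nuclear factor of exhausted T cells, at 2.84. Of 19 effector surface markers 16 were higher and 1 lower (median 2.57), with Tnfrsf9, the gene of 4-1BB, at 4.02 and Klrc1, a lectin-like receptor, at 3.82. Effector and memory regulators had 9 of 16 higher and 2 lower (median 1.27), and chemokines 7 of 9 higher and 0 lower (median 2.0).

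The medians of the neutrophil, macrophage, dendritic cell and erythroid lists in CD8 after against at transplant lay above their random ranges, beside these effector, surface and chemokine genes. Of 13 neutrophil genes 10 were higher and 0 lower (median 2.92), with S100a9, an abundant neutrophil protein, from 1265 to 9220.0. Of 19 macrophage and monocyte genes 12 were higher and 0 lower (median 1.28, or 1.48 with Cd14 at its bound), with Lyz2, a lysozyme, from 671 to 2464. Of 14 dendritic cell genes 7 were higher and 1 lower (median 1.03), of 13 erythroid and platelet genes 11 and 0 (median 2.67), and of 13 NK cell genes 4 and 4 (median 0.71).

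Most helper subset lists also had medians above their random ranges in CD8, with 9 of 12 Th1 genes (median 1.90), 6 of 7 Th17 genes (3.05, or 3.45 with Il23r at its bound) and 6 of 9 follicular helper genes (2.02) at least 2-fold higher and only Cxcr5, a receptor that guides cells to B cell follicles, lower (-1.27). Il21 went from 1 read to 128, a ratio of 219 (38.5 to 8701). Of 7 Th2 genes 3 were higher and 2 lower (median 0.82, or 2.19 with Il13 at its bound). Regulatory T cell genes had 10 of 17 higher and 3 lower (median 1.63), and Foxp3 went from 20.8 to 74.1, a ratio of 3.57 (2.21 to 6.08). Il10, an anti-inflammatory cytokine, was at 0 and then at 97.3, at least 39.3-fold higher. Genes of gut homing and migration went both ways, with 8 of 20 higher and 7 lower (median 0.51). Besides Ccr9, the lower genes held Itgae, the gene of CD103, which retains T cells in epithelium (log2 ratio -3.89), and Gpr15, a receptor of the colon (-2.31), whereas Gcnt1, an enzyme of selectin ligands, had 3.99 and Cxcr6 1.99.

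Of the remaining lists, the interferon gamma median had the opposite sign in CD8 and CD4, but in CD8 it lay within its random range. The housekeeping and CD4 lineage medians also had opposite signs on the deposited scale but changed sign in CD4 under other scalings. In CD8 the heat shock, immediate early, apoptosis, NFkB, gamma chain, T cell identity, housekeeping and both lineage medians lay within their ranges too. Glycolysis had 10 of 17 genes higher (median 1.28), oxidative phosphorylation 1 of 22 (0.47), and cytosolic ribosomal proteins 16 of 30 lower (-1.01). Type I interferon genes had 2 of 24 higher and 5 lower (median -0.51, percentile 0.11), with Oas2, an antiviral synthetase, at -2.45 and Ifih1, a sensor of viral RNA, at 1.61. The interferon gamma list had 1 of 20 higher and 0 lower (median -0.11), the heat shock list 0 and 5 of 15 (-0.49), and immediate early genes 1 and 4 of 18 (-0.34). Apoptosis regulators had 4 of 14 higher and 2 lower (0.27), NFkB and costimulation 4 of 16 and 0 (0.31), and gamma chain receptors 3 of 8 and 2 (0.06, or 0.27 with Il9r at its bound). T cell identity genes had 0 of 12 higher and 1 lower (-0.39) and housekeeping genes 3 of 14 and 0 (0.24). The CD4 lineage list had 2 of 7 members higher and 2 lower in CD4 cells (median -0.08) and 2 higher and 1 lower in CD8 cells (0.44). The CD8 lineage list had 4 of 10 higher and 0 lower in CD4 cells (median 0.85), among them Nkg7, a granule membrane protein (3.50), and 1 higher and 2 lower in CD8 cells (0.04). 

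**Figure D2:**
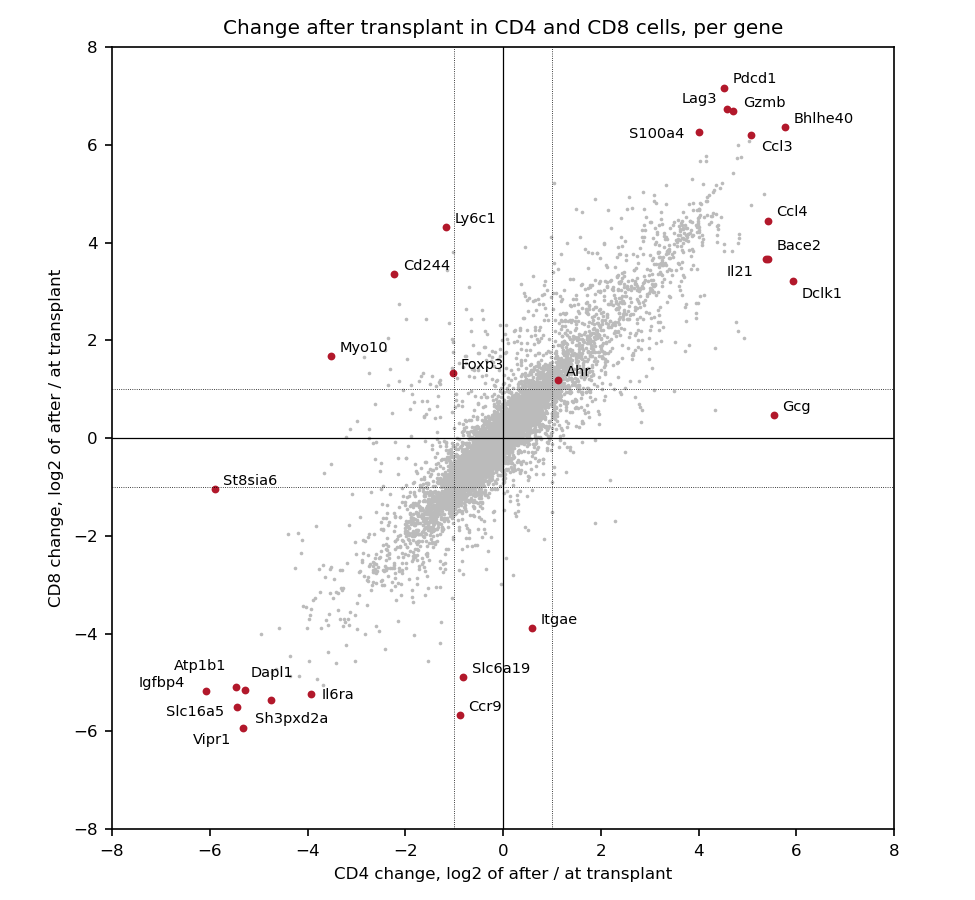
Each grey point is 1 of 9933 genes, with its log2 ratio after against at transplant in CD4 cells on the x axis and in CD8 cells on the y axis, and dotted lines mark 2-fold. Most genes lie along the diagonal (Pearson r 0.89), while Ccr9 (-0.89 and -5.66), Itgae (0.60 and -3.89) and Cd244 (-2.22 and 3.36) lie far from it.

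The ratios after against at transplant were similar in the 2 cell types. Across 9933 genes, which are not independent replicates, Pearson's r was 0.89 and Spearman's rho 0.88, and the 2 ratios share no library. The pools of mice were made before the sort, however, so the CD4 and CD8 libraries of a time may share mice. Any difference between pools would then enter both ratios. Of the genes higher in CD4, 86.4% were also higher in CD8, and of those lower in CD4, 72.8% were also lower. In all 1040 genes were higher in both, against 181 for independent lists, and 784 lower in both, against 119. The share with the same direction was 80.0% of the genes beyond 2-fold in CD4 (95% interval 78.3 to 81.6%, exact binomial). Opposite directions beyond 2-fold were seen for 35 genes, of which 32 were lower in CD4 and higher in CD8. The other 3 were 5830411N06Rik and Cd163l1, scavenger receptor genes of gamma delta T cells, and Ms4a4c, which was named after its values were seen (615 to 1252 in CD4, 1964 to 681 in CD8).

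The difference of the 2 log2 ratios passed 2-fold for 201 genes in favour of CD4 and 399 in favour of CD8, and it was given as a value with no test. It was computed with the pseudocount, and those of Gcg and St8sia6 rest on a CD8 library at 0. Among named genes, with a mean of at least 10 ppm, the largest differences in favour of CD4 were those of Gcg (5.07), Ccr9 (4.77), Itgae (4.48) and Slc6a19, a transporter of neutral amino acids (4.08). Apart from Gcg, these genes were low in CD4 at both times and lower after transplant in CD8: Itgae stood at 56.4 and 92.9 in CD4 and at 2581 and 161 in CD8. In favour of CD8 they were Cd244, a receptor of the SLAM family (-5.58), Ly6c1 (-5.49), Myo10, an unconventional myosin (-5.19), and St8sia6 (-4.84). Ly6c1, a surface antigen of T cells and monocytes whose reads cannot be told cleanly from those of Ly6c2, went from 1898 to 834 in CD4 and from 33.2 to 940.5 in CD8. Myo10 went from 653 to 43.8 in CD4 and from 10.7 to 66.3 in CD8. The macrophage list differed between CD4 and CD8 at transplant by a median of 2.48 and after transplant by 0.12, a measured fact that stands beside the genes in favour of CD8.

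**Figure D3:**
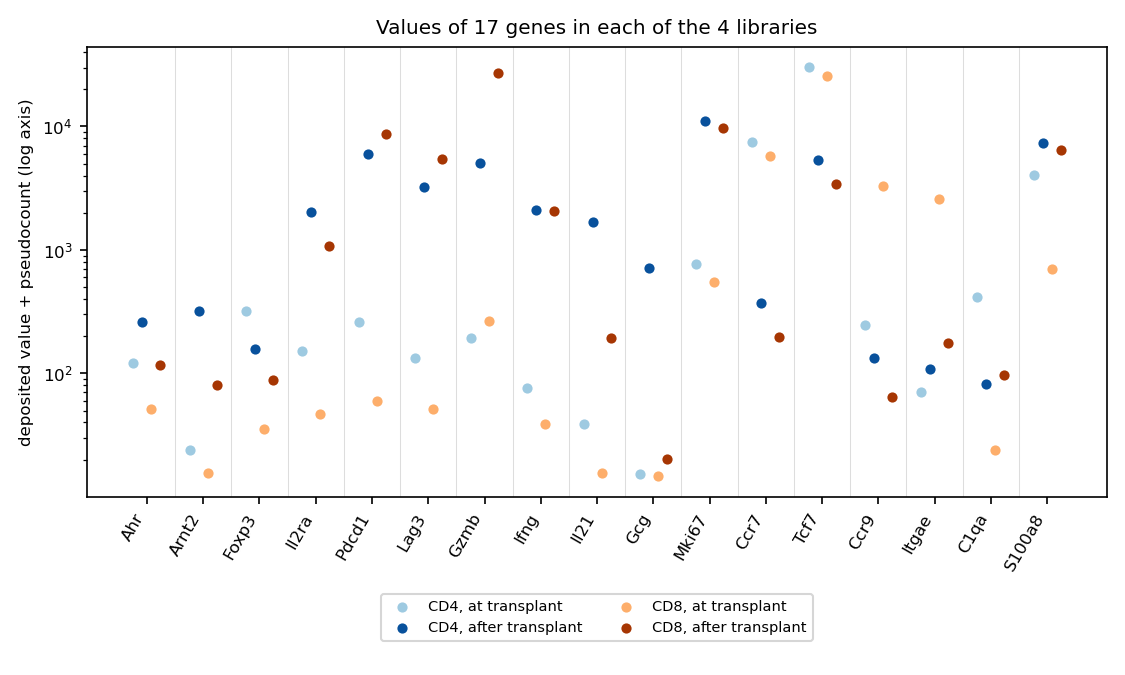
Points give the deposited normalised value plus 14.7 of 17 genes in each of the 4 libraries (y axis, log scale; x axis, genes picked from those named in the text after their values were seen). Without the added 14.7, Gcg reached 696 only in the CD4 library after transplant, and Ccr9 3252 only in the CD8 library at transplant.

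At transplant the CD4 and CD8 libraries differed in their lineage genes and in genes of other cells. Of 9933 genes 489 were higher in CD4 and 147 higher in CD8, and 93.6% lay within 2-fold. Under median of ratios scaling the numbers became 412 and 182, so that the share in favour of CD4 moved from 76.9% to 69.4%. Counting intervals lay wholly beyond 2-fold for 426 and 124 genes, and the counts at the 2-fold mark were 193 and 87 of 7502 genes under the stricter filter and 912 and 190 of 15868 with no filter. Besides Cd4, the largest ratios of named genes (mean of at least 10 ppm) in favour of CD4 were those of Cd40lg, the ligand that activates B cells (6.03), Zbtb7b, the gene of ThPOK, which specifies the CD4 lineage (5.40), St8sia6 (5.35) and Ly6c1 (5.32). In favour of CD8, besides Cd8a (-6.79) and Cd8b1 (-5.66), they were Itgae (-5.19), Slc6a19 (-4.56) and Bend4 (-4.42). Of 7 CD4 lineage genes 5 were higher in CD4 (median 2.55), and of 10 CD8 lineage genes 8 were higher in CD8 (median -2.55), including Nkg7 (-3.44) and Crtam, an adhesion molecule (-2.58). Foxp3 was 14.7 times as high in CD4 (9.87 to 23.1), and the regulatory T cell list had 10 of 17 members higher in CD4 (median 1.67). Ahr was higher in CD4, at 2.84 times the CD8 value (2.03 to 4.05). The AhR and partner list had medians of 0.20 at and 0.11 after transplant between CD4 and CD8. Maf, a transcription factor of helper subsets, had a log2 ratio of 4.39, and the inhibitory list 8 of 15 members higher in CD4 (median 1.37). S phase genes all lay within 2-fold, and their median of -0.01 lay below its random range (percentile 0.92). In contrast, 1 of 22 genes of the G2 and M phases was higher in CD4 and their median of 0.40 lay above its random range (percentile 100).

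The medians of the neutrophil, macrophage, dendritic cell, NK cell and erythroid lists, CD4 against CD8 at transplant, lay above their random ranges. Which cells the flow sort let through was not measured here. All 13 measured neutrophil genes were higher in CD4 (median 2.25), as were 17 of 19 macrophage and monocyte genes (median 2.48, or 2.75 with Cd14 at its bound), 8 of 14 dendritic cell genes (1.47), 8 of 13 NK cell genes (1.16) and 5 of 13 erythroid genes (0.83), while 2 NK cell genes were lower and the other 8 erythroid genes lay within 2-fold. C1qa, a complement gene of macrophages, stood at 404 in CD4 and 9.08 in CD8, S100a8, a neutrophil protein, at 4026 and 679.7, and Cd74, the invariant chain of class II molecules, at 4775 and 1086. Innate lymphoid genes had 6 of 14 higher in CD4 (median 0.95), but 9 of the 14 stand in lists of T cell genes. Their medians after against at transplant were -0.04 in CD4 and 0.47 in CD8, or 1.12 with Il13 at its bound. Plasma cell genes had 2 of 4 higher in CD4 (1.2), with medians after against at transplant of -0.98 in CD4 and 0.54 in CD8. Gamma delta T cell genes had 1 of 4 higher and 2 lower in CD4 (-1.17), and medians after against at transplant of 2.08 and -0.97. With Il23r at its bound the median between CD4 and CD8 became -1.0. The B cell list had 2 measured members, Cd79b (-2.31) and Cd22 (0.40), and the stroma and endothelium list 1, Pecam1 (0.86), too few for medians.

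**Figure D4:**
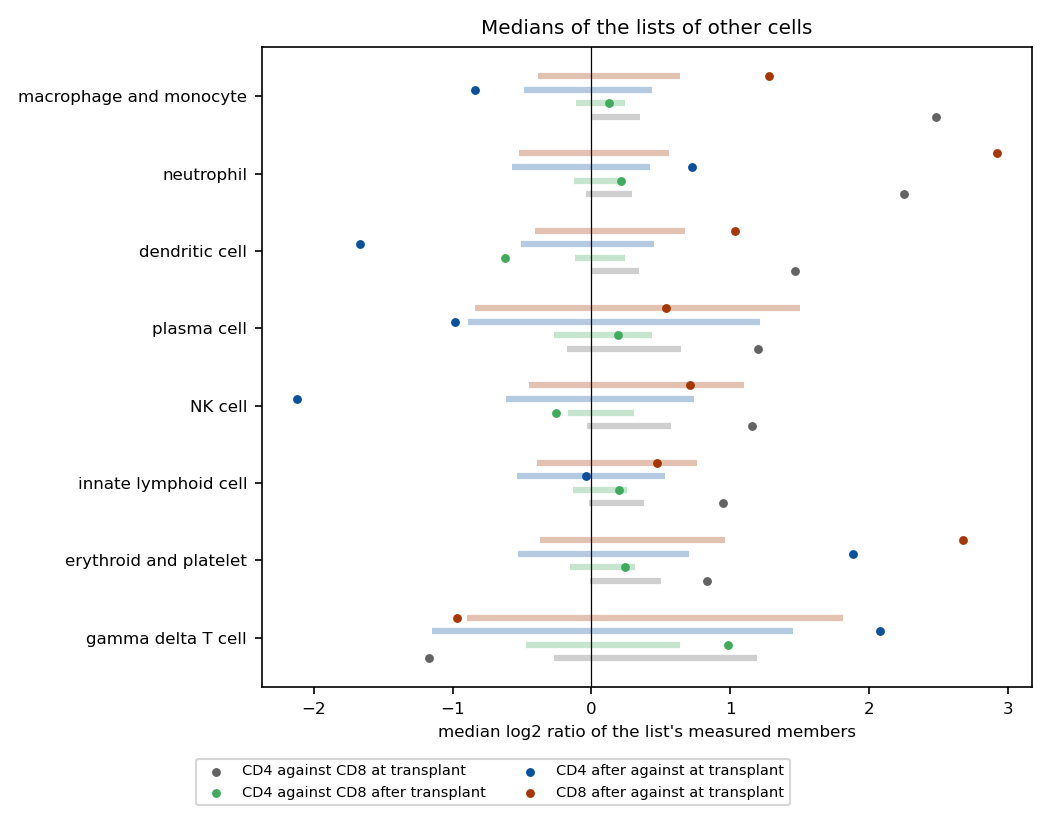
Points give the median log2 ratio of 8 lists of other cells in the 4 comparisons (x axis, log2 units; y axis, lists), and bars the range that holds 95% of 10000 random lists. The macrophage list stood at 2.48 between CD4 and CD8 at transplant and at 0.12 after transplant, and that of innate lymphoid genes in CD4 after against at transplant, -0.04, changed sign under other scalings.

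After transplant the CD4 and CD8 libraries were closer, with 240 genes higher in CD4 and 95 higher in CD8 and 96.6% within 2-fold. Here the counting interval lay wholly beyond 2-fold for 151 and 74 genes, and the counts at the 2-fold mark were 126 and 44 under the stricter filter and 375 and 188 with no filter. The ratios at and after transplant had a Pearson's r of 0.40 and a Spearman's rho of 0.35 across genes, and 92 genes were higher in CD4 at both times, against 11.8 for independent lists. Cd4 (7.29), Cd40lg (5.30), Gcg (5.13), Tnfsf11, the gene of RANKL (3.65), and Igfbp7 (3.34) had the largest ratios of named genes (mean of at least 10 ppm) in favour of CD4. Gcg stood at 696 in CD4 and 5.64 in CD8 (794 and 4 reads), a ratio of 123 (48.0 to 454). In favour of CD8 they were Cd8a (-5.86), Cd8b1 (-4.82), Gzma (-3.81), Prf1 (-3.36) and Cd244 (-3.30). Of 16 cytotoxic genes 5 were higher in CD8 and 2 higher in CD4 (median -0.68), with Gzmb at 5026 in CD4 and 27271 in CD8 and Ifng at 2072 and 2039. Of 19 effector surface markers 7 were higher in CD8 and 3 in CD4 (median -0.74), with Klrk1, the gene of NKG2D, at -3.21 and Tnfrsf4 at 2.23. All 7 CD4 lineage genes were higher in CD4 (median 1.95), and 6 of 10 CD8 lineage genes higher in CD8 (-1.68). In favour of CD4 stood 4 of 7 Th2 genes (median 1.56), 5 of 16 NFkB and costimulation genes (0.88) and 7 of 17 regulatory T cell genes (0.90), with Ebi3, a subunit of interleukin-35, at 3.01. Ahr was 2.40 times as high in CD4 (1.85 to 3.15). The macrophage, neutrophil, erythroid and NK cell lists had medians of 0.12, 0.21, 0.24 and -0.25, and the dendritic cell list -0.62.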

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

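These results were set apart because the log2 ratio after against at transplant had opposite signs in CD4 and CD8 cells, beyond 2-fold in each for the named genes and outside the range of random lists in each for the lists. The differences below are CD4 minus CD8 and were not tested, since each group held 1 library. The tests weighed for this pattern were all chosen after the result was seen.

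Among genes of macrophages and antigen-presenting cells the difference was -4.39 for C1qa, -4.0 for C1qb and -4.88 for C1qc, the 3 chains of complement C1q, -3.43 for Emr1, the macrophage antigen F4/80, and -4.50 for Vcam1, an adhesion molecule. It was -2.99 for Fcer1g, an Fc receptor subunit, -4.41 for Itgax, the gene of CD11c, -2.47 for Cd74, and -2.97, -2.89 and -2.95 for the class II genes H2-Aa, H2-Ab1 and H2-Eb1. The difference of the list medians was -2.12 for macrophage and monocyte genes and -2.70 for dendritic cell genes. Among genes of T and NK cells it was -5.58 for Cd244, -4.58 for Gzma, -3.46 for Zbtb7b, -2.36 for Foxp3 and -5.49 for Ly6c1, and Myo10 and Lpcat2 had -5.19 and -2.16. In the other direction stood Cd163l1 at 4.0, 5830411N06Rik at 3.61, and the median of the gamma delta T cell list at 3.05, in which these genes are 2 of the 4 measured members.

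The pattern was that 32 genes were at least 2-fold lower after transplant in CD4 and at least 2-fold higher in CD8. The difference of the 2 log2 ratios equals the log2 ratio of CD4 to CD8 after transplant minus that at transplant, so these genes had to differ between the cell types at 1 time or both. At transplant their median log2 ratio of CD4 to CD8 was 2.81 (range 0.77 to 5.40), after transplant it was -0.29, with 4 genes at -1 or lower, and 13 of the 32 stand in lists of other cells, while 22 of the 32, Foxp3 not among them, passed 2-fold both ways under every one of 4 other scalings. The macrophage list, CD4 against CD8 at transplant, had a lowest median of 2.31 over these scalings, so they did not remove its difference. The largest shift they gave the median of all genes in that comparison was -0.18, so a larger shift was not tested. This list also does not test the 32 genes. Macrophages and dendritic cells in the CD4 library at transplant may account for part of the pattern, but the values that show the pattern cannot test this. Which cells the sort for CD4 let through was not measured. For Foxp3, Zbtb7b, Gzma and Cd244 a difference in T or NK cell makeup stays open and untested too.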

How the results depend on the processing

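Across the alternatives 64 of 76 gene counts stayed within 1.5 times the main value. Of 1172 list medians 1135 kept their side of the random range, 16 left it and 17 entered it. The other 4 were outside it in the main analysis and changed sign. Those of oxidative phosphorylation stayed below the range (percentiles 0.8, 1.2 and 0.9), and that of plasma cells entered it (51.3). Of the 148 medians 19 changed sign under at least 1 setting, the largest of them 0.98 in size in the main analysis and 2 of them outside the random range there. Of 3762 ratios of named genes, which are 627 ratios repeated over the settings, 2564 lay within the counting interval. That interval holds no pseudocount, whereas these ratios do. Ratios of genes near the floor, such as Gcg in CD4, therefore lay outside it in the main analysis too. Of the named ratios beyond 2-fold 0 were reversed, and 10 of 12 ratios of Ahr stayed within their intervals. Other scalings moved the median of all genes by more than 0.1 in 3 cases: -0.16 (trimmed mean of M-values) and -0.18 (median of ratios) between CD4 and CD8 at transplant, and 0.15 (equal totals) in CD4 after transplant. The oxidative phosphorylation median between CD4 and CD8 at transplant, 0.01, became -0.16, -0.18 and -0.0728 under trimmed mean, median of ratios and equal totals, and the plasma cell median in CD4 after transplant, -0.98, became 0.0055 with no filter, when 8 members in place of 4 counted. The share of genes with the same direction in CD8 as in CD4, 80.0%, was 82.9% with equal totals, 73.8% with no filter and 82.2% with the stricter filter. It was 82.0% over the 9519 genes left without genes of other cells, which decides nothing, as some genes were left out for the ratios that are compared. The log2 ratio of Ahr with a pseudocount 4 times as large was 0.90 in CD4 and 0.75 in CD8. That pseudocount also gave 316 genes higher in CD4 than CD8 at transplant and 158 after it, against 489 and 240. No filter admitted 15868 genes, with 912 higher in CD4 than CD8 at transplant, and 375 higher and 188 lower after it, against 489, 240 and 95. The stricter filter left 7502 genes, with 728 higher after transplant in CD4 and 886 in CD8, against 1204 and 1490, and between CD4 and CD8 193 higher and 87 lower at transplant and 126 and 44 after it, against 489, 147, 240 and 95. Counting intervals wholly beyond 2-fold, added later, were found for 151 genes higher in CD4 than CD8 after transplant, against 240. The changes of the counts under the filters arise from which genes were admitted, and not from their number alone. Genes higher in CD4 than CD8 at transplant were 193 of 7502 with the stricter filter, against 489 of 9933. For the other changes the cause was not tested.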

Other observations

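Gene families outside the fixed lists were looked at after those lists had been seen, as 23 families ranked among 1000 random lists each, and they describe these libraries only. Genes of DNA repair by homologous recombination were higher after transplant in both cell types, 13 of 14 in CD4 (median log2 ratio 2.64) and 13 of 14 in CD8 (2.87). Serpins, inhibitors of proteases such as granzymes, had 11 of 13 higher in CD4 and 12 in CD8 (medians 2.95 and 3.04), with Serpina3f at 5.34 in CD4 and Serpine2 at 5.19 in CD8. S100 calcium-binding proteins had medians of 1.17 and 2.30 and annexins, membrane-binding proteins, of 0.49, within its random range, and 1.89, led by S100a4 (4.02 and 6.26) and Anxa2 (3.13 and 4.0). Neutrophil genes, which include S100a8 and S100a9, had medians of 0.72 and 2.92 beside them. TNF ligands were higher in 7 of 7 cases in CD4 and 4 in CD8, with Tnfsf4, the ligand of OX40, at 2.42 and 4.11.

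Zinc finger proteins of the Zfp series, mostly repressors of transcription, were lower in 44 and higher in 10 of 296 in CD4, and lower in 46 and higher in 12 in CD8 (medians -0.42 and -0.39, percentile 0 in each). Proteasome subunits had medians of 0.53 and 0.74, one-carbon and serine metabolism 0.72 and 1.01, with Tyms, thymidylate synthase, at 3.0 and 3.07, and kinesins 0.98 and 0.83, with Kif11, a mitotic motor, at 4.01 and 4.70. Genes of cholesterol synthesis and uptake were lower in 3 and higher in 0 of 19 in CD4 (median -0.51, percentile 0.9), and higher in 4 and lower in 0 in CD8, where the median of 0.33 lay within its random range. Killer lectin-like receptors had medians of -0.52, at the edge of its random range (percentile 2.5), and 0.71, within its range. Beside them the NK cell list had medians of -2.12 and 0.71.

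Of the tests that follow, those on the sum of 4 marker genes and on Dpp4 and Fap together were written before their results were seen, and those on all endocrine and gut genes, Dpp4 alone, Fap against Gcg, counting error, scaling and regulatory T cell genes were chosen afterwards. Gcg stood at 696 in the CD4 library after transplant and at 0.664, 0 and 5.64 in the CD4 library at transplant and the CD8 libraries at and after transplant, and counting error does not account for this, as the lower bound of the ratio of CD4 to CD8 after transplant was 48.0. Endocrine or gut cells are argued against: 0 of their 22 listed genes reached 10% of Gcg in that library and 12 were at 0, among them Ttr, Chgb, Pyy, Ins1, Ins2, Krt8 and Fabp2, while the highest, Cdh17, stood at 41.2, and at 52.2 in CD8. The preset sum of Ttr, Chga, Pcsk2 and Krt8, 1.13% of Gcg, fell between its bounds of 1 and 10%. For transcription running on from the neighbouring Dpp4, the log2 ratio of Dpp4 was 0.30 in CD4 against CD8 after transplant (ratio 1.23, counting interval 1.15 to 1.32). A higher level of Dpp4 therefore does not account for Gcg. Transcription running on from Dpp4 at a similar level stays open, as strand, splicing and coordinates were not analysed. For Fap the preset comparison gave a log2 ratio of 0.92, set by the pseudocount as Fap was at 0 in CD8, but Fap had 15 reads against 794 of Gcg in that CD4 library, or 1.89% of its value (95% counting interval 1.05 to 3.14%), too few to supply it, and a transcript made by T cells was not tested.

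Foxp3 was lower after transplant in CD4, from 305 to 141. Counting error is argued against by an upper bound of the ratio of 0.555. The highest log2 ratio over 4 other scalings was -0.89, so these scalings did not remove the decrease. The largest shift they gave the median of all genes in this comparison was 0.15, so a larger shift was not tested. The decrease fell short of 2-fold under 3 of the scalings, and the counting interval held 2-fold. A smaller share of regulatory T cells may explain it, but the 6 genes Foxp3, Ikzf2, Ikzf4, Gpr83, Nrp1 and Folr4 had a median log2 ratio of -0.59 with 4 below and 2 above 0, which leaves this open, and lower Foxp3 per cell was not tested.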
